A study of Mus musculus with 25 samples.

How the data were processed

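RNA was sequenced from neurons sorted by NeuN and astrocytes sorted by Gfap from brains of mice aged 6 months, either carrying a human tau transgene with the P301S mutation or non-transgenic littermates (non-Tg). The 25 libraries were 6 P301S neuron, 8 non-Tg neuron, 5 P301S astrocyte and 6 non-Tg astrocyte libraries. Cd11b+ myeloid cells were sorted in the same experiment and are not analysed here. The labels do not say whether a library is 1 animal or a pool, so the p-values measure the spread between these samples. Nor do they tie neuron and astrocyte libraries to animals, so a neuron and an astrocyte library may share an animal and were treated as independent.

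Each deposited file gives a count per gene: per the file headers, reads uniquely aligned to a gene model. A second deposited column holds size-factor-adjusted RPKM computed by the authors. It equals the counts times 1 factor per sample and 1 per gene, with a largest relative deviation of 9.55e-15, so the counts were used throughout. Per the submitters' processing notes, GSNAP and the mouse build GRCm38 were used; the version and role of the aligner and the version of the gene models are not given in the sources used here. The 36528 Entrez gene IDs were matched to symbols and to RefSeq positions on GRCm38.p6. 5479 IDs had no match; they held 3.30% of all counts and stayed in every test under their ID. 5729 IDs were at 0 in every library.

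Total counts per library ran from 1.25e+06 to 4.45e+06. A floor of 3 counts corresponded to 0.674 to 2.41 CPM (counts scaled to a library total of 1e+06) across libraries. Floors cover counting error only, because reads without molecular identifiers are not independent molecules. Bootstrap intervals (10000 draws) cover the spread between genes for a median and between libraries for a level. Levels are given as CPM scaled by the TMM method, as mean ± SD over the libraries of a group, and come from the fit of 1 cell type unless stated.

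Genotype was compared within each cell type with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr at its default settings and a robust fit. A prior count of 2 was set for the log2 CPM behind the list tests and marker covariates described below, not for the fitted fold changes. The difference of the genotype effect between cell types (astrocytes minus neurons), and neurons against astrocytes within non-Tg, were tested in 1 fit of all 25 libraries with a mean per group. That fit gave each gene 1 spread for both cell types. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison. The SE of a log2 fold change was its size divided by the square root of F.

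34 gene lists (cell type markers, stress and signalling pathways) were fixed in advance. Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, and adjusted over the lists of a comparison. Each list was tested again with an estimated correlation and with fry, whose p tests whether a list's genes move on balance in 1 direction, without comparing them with other genes. Members were also counted as rising or falling over all genes and as adjusted over the list alone.

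The genes named were set by rule. They are the 8 higher and 8 lower genes with the smallest p among those called with a log2 change of at least 0.5. Predicted or unnamed genes, Xist and Y-linked genes were left out of that part. The rule adds up to 4 members with the smallest p of each list that was called or had a called member, and Mapt, Prnp, Gfap, Apoe, C3 and C4b in any case. For the difference between cell types only the 8 genes per direction were taken, and for neurons against astrocytes only list members. Genes named outside the rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here. The groups, comparisons, lists, rule and other settings to be tried were fixed before the data were examined.

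Per-library measures were compared by exact permutation tests, 2-sided, with adjustment over the 11 tests. Genes detected were also counted after thinning each library to 1e+06 counts.

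The other settings fixed in advance were RLE size factors, DESeq2 1.42.0, limma voom with sample quality weights, no filter, a filter at 1 CPM and all 25 libraries in 1 fit. Covariates for sex marker genes (Xist minus Y-linked genes) and for the marker levels of oligodendrocytes and microglia were added in turn. Fits were also run without 2 non-Tg neuron libraries whose sample identifiers fall in another range, and without each library in turn. The gene lists were tested with fry and with an estimated correlation, and the cell type comparison with the 14 non-Tg samples alone. Chosen after seeing the data were the authors' size factors, a covariate for genes detected, leaving out P301S astrocyte libraries 3 and 4, and leaving out Malat1 and mitochondrial genes. A minimum of 3 tested members per list, and the lists without the 2 libraries of the other identifier range, were chosen after seeing the data as well. Each count was compared with those of 100 splits of the same libraries into groups of the same sizes.

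The pipeline was tested on simulated counts with the sizes and spread of each comparison. In the same run 100 genes were changed by 1 on the log2 scale and another 100 by 2. Counts were drawn independently for each gene, without quality differences between libraries. Each gene had 1 spread in all libraries of a comparison, so a difference in spread between cell types was not simulated. Of genes changed by 1 on the log2 scale edgeR recovered 55% in neurons, 2% in astrocytes, 2% for the difference between cell types and 13% between cell types. At a log2 change of 2 the shares were 99%, 25%, 17% and 60%. The false calls numbered 14, 2, 2 and 0, and no gene was called when nothing was changed in either cell type. camera recovered a shifted list in both cell types, with 2 other lists called in neurons and 0 in astrocytes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.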

Results

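Each library held between 1.25e+06 and 4.45e+06 counts. In units of 1e+06 counts, group means were 1.96 ± 0.267 (SD, n = 6) in P301S neurons, 2.23 ± 1.15 (n = 8) in non-Tg neurons, 3.32 ± 0.488 (n = 5) in P301S astrocytes and 3.0 ± 0.741 (n = 6) in non-Tg astrocytes. P301S astrocyte libraries detected fewer genes than non-Tg ones at a depth of 1e+06 counts, 14021 ± 1617 (n = 5) against 16698 ± 1043 (n = 6; exact permutation test, 2-sided, p = 0.0130, adjusted p = 0.0595 over 11 tests). Their mitochondrial share of counts was 7.72% ± 2.86 against 4.04% ± 1.52 (exact permutation p = 0.0216, adjusted p = 0.0595). In neurons the same measures were 18156 ± 262 (n = 6) against 17977 ± 432 genes (n = 8; exact permutation p = 0.380, adjusted p = 0.574) and 1.52% ± 0.468 against 1.11% ± 0.349 (exact permutation p = 0.0826, adjusted p = 0.182). Malat1, a nuclear non-coding RNA, took 30.4% ± 5.52 of the counts in P301S astrocytes and 32.9% ± 1.86 in non-Tg astrocytes. In neurons it took 23.6% ± 2.72 and 23.1% ± 1.64.

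**Figure D1:**
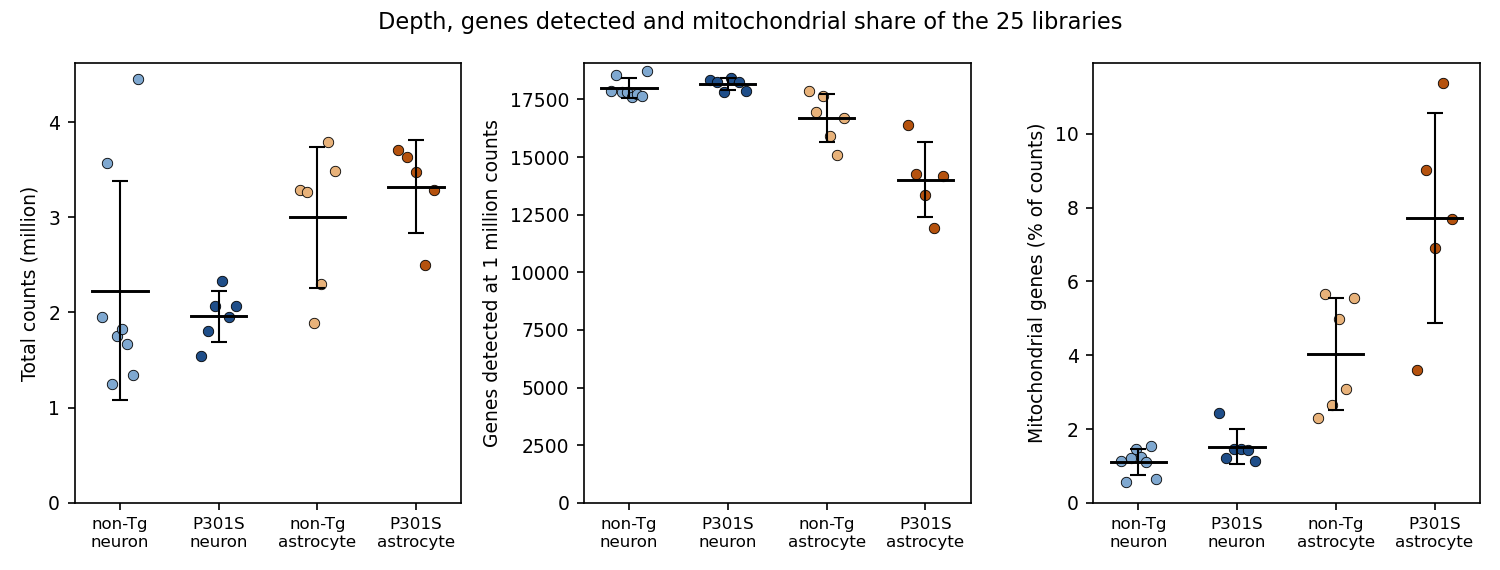
Total counts in units of 1e+06, genes detected at a depth of 1e+06 counts, and mitochondrial share of counts in percent for each of the 25 libraries, by group. Points are libraries, bars are group means and error bars are SD; P301S astrocyte libraries averaged 14021 genes and non-Tg astrocyte libraries 16698.

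The sorts separated the cell types. Among non-Tg libraries (8 neuron, 6 astrocyte), 13 of 15 tested neuron markers were higher in neurons, with a median log2 difference of 2.30 (adjusted p = 1.61e-06). Rbfox3, which encodes the sorted antigen NeuN, was higher by 3.79 (SE 0.48) and the synaptic vesicle calcium sensor Syt1 by 3.88 (SE 0.30). The exceptions were Tubb3 (1.23) and Nefl (0.26), a tubulin and a neurofilament gene. All 16 astrocyte markers were lower in neurons, with a median of -5.97 (adjusted p = 8.51e-18), among them the glutamate transporter gene Slc1a2 (-5.59, SE 0.21), the water channel gene Aqp4 (-7.37, SE 0.36) and Gfap (-6.36), the antigen of the astrocyte sort. All 15 genes of astrocyte transport and metabolism were lower (median -6.22, adjusted p = 3.44e-17).

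All 10 dentate granule neuron markers were higher in neurons (median 3.41, adjusted p = 4.76e-06), as were 10 of 13 excitatory markers with 2 lower (median 2.83, adjusted p = 0.0106). 6 of 8 inhibitory markers were higher and 1 lower, a list that was not called (adjusted p = 0.123). 15 of 20 postsynaptic genes (median 1.84) and 13 of 18 presynaptic genes (median 2.04) were higher. Oligodendrocyte markers were lower in neurons in 9 of 9 cases (median -2.66, adjusted p = 4.38e-04) and oligodendrocyte precursor markers in 5 of 6 (median -4.33; adjusted p = 0.0110, and 0.0669 with an estimated correlation). Of 8 mural and fibroblast markers 5 were lower and 1 higher (adjusted p = 0.0224). None of 9 microglia and myeloid markers differed (median 0.35, adjusted p = 0.937). Over the 14197 genes tested, 3097 were higher and 3562 lower in neurons; the median over all genes was -0.11, and 0.08 with RLE size factors.

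In P301S astrocytes, reactive astrocyte and interferon response genes were higher as lists, and the complement genes C4b and C4a rose. C4b, a complement component, rose from 136 ± 57.8 CPM (n = 6) to 719 ± 125 CPM (n = 5), a log2 change of 2.41 (SE 0.28, adjusted p = 1.03e-04). Serpina3n, a secreted protease inhibitor induced in inflammation, rose from 26.5 ± 19.4 to 273 ± 61.5 CPM (3.36, SE 0.40, adjusted p = 1.52e-04). Gfap, the intermediate filament gene of reactive astrocytes and the gate of the sort, rose from 175 ± 90.6 to 820 ± 143 CPM (2.22, SE 0.30, adjusted p = 5.12e-04). Oasl2, an interferon-induced gene, rose from 12.2 ± 8.46 to 196 ± 146 CPM (4.0, SE 0.53, adjusted p = 5.12e-04). Each was above the non-Tg mean in 5 of 5 P301S libraries.

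On GRCm38, C4b (ID 12268) lies on chromosome 17 from 34728139 to 34743902, Serpina3n (ID 20716) on chromosome 12 from 104406646 to 104414334, and Gfap (ID 14580) on chromosome 11 from 102887336 to 102897200. The counts of C4b differed by 0.0440% from those of 1 unmatched gene ID, which was called too, and C4a is a close paralog annotated as a transcribed pseudogene. The other genes with the smallest p were Ssc5d (3.8, SE 0.52), a scavenger receptor family gene, Fxyd1 (2.06, SE 0.31), a regulator of the sodium pump, Aspg (3.26, SE 0.50), an asparaginase gene, and C4a (2.60, SE 0.40). The 3 lower genes were Dcdc5, from 9.55 to 0.152 CPM on average below the floor of 3 counts in P301S libraries, Tlcd4, a membrane protein gene, from 44.4 ± 6.00 to 6.15 ± 4.77 CPM (-2.81, SE 0.57, adjusted p = 0.0218), and the phosphatase gene Ptpn4, from 143 to 53.6 CPM (-1.42, SE 0.32, adjusted p = 0.0413).

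Pan-reactive astrocyte genes, induced in astrocytes by several kinds of injury, rose in 6 of 9 tested cases, with 8 adjusted over the list alone and a median log2 change of 2.03 (adjusted p = 2.59e-18). They included Osmr (1.96, SE 0.34), the receptor for oncostatin M, and Vim (2.03, SE 0.36), a filament gene named after its value was seen. A1 reactive astrocyte genes were called higher as a list (median 2.09, adjusted p = 9.61e-05), with Ggta1 (2.08, SE 0.43), a glycosyltransferase gene, the 1 of 6 that rose and 4 adjusted over the list alone. Serping1, an inhibitor of complement C1, had a value of 2.10 (adjusted p = 0.192), and 3.17 without non-Tg astrocyte 4. Interferon response genes were called (median 1.96, adjusted p = 9.66e-09). Oasl2 and the transcription factor gene Stat2 (1.66, SE 0.34) rose among 11, with 7 adjusted over the list alone. Ifit1 (2.78, SE 0.64, adjusted p = 0.0507) did not pass over all genes. MHC class I genes were called with 0 of 7 members past the threshold and 4 adjusted over the list alone (median 1.78, adjusted p = 6.43e-04), but not with a sex marker covariate (adjusted p = 0.0675, the highest of 26 alternatives). Their smallest p values were those of B2m (1.78, and 1.13 without P301S astrocyte 4), Nlrc5 (2.43) and Tap2 (2.22), for antigen presentation.

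Complement genes were called, with C4b and its close paralog C4a the 2 of 10 that rose and 5 adjusted over the list alone (median 1.04, adjusted p = 1.67e-06). Whether C4b and C4a are separate signals was not tested. Clu (0.84), C1qb (2.76) and C3 (1.23, SE 0.67, adjusted p = 0.429) did not pass. C1qb rests on P301S astrocyte 3 (0.71 without it), and C3 was 0.74 without P301S astrocyte 1. Of the disease-associated microglia genes, 10 of 11 had been higher in non-Tg astrocytes than in non-Tg neurons. Among the 10 tested for genotype in astrocytes, Gpnmb (1.95, SE 0.39), a lysosomal glycoprotein gene, rose, and 5 rose adjusted over the list alone (median 1.13, adjusted p = 7.90e-07). Ctsb, a lysosomal protease gene, had a value of 1.10 (adjusted p = 0.0956). Cholesterol synthesis genes were lower as a list (median -0.92, adjusted p = 6.82e-06), with 0 of 17 past the threshold and 3 lower adjusted over the list alone. Cyp51 (-1.76, SE 0.47, adjusted p = 0.0964) and Insig1 (-2.13, adjusted p = 0.124), an enzyme and a regulator of the pathway, had the smallest p values. Lysosome and autophagy genes were called (median 0.52, adjusted p = 0.0168; adjusted p = 0.0982 with an estimated correlation), with 0 of 20 past the threshold and 2 adjusted over the list alone. Astrocyte markers were called too (median 0.26, adjusted p = 0.0414; adjusted p = 0.346 with an estimated correlation), with Gfap the 1 of 16 that rose and 3 adjusted over the list alone. The astrocyte marker call was lost in 13 of 26 alternatives, DESeq2 and voom among them. Without 1 library its adjusted p reached 0.176. Aldh1l1 (1.59, adjusted p = 0.0806) and the gap junction gene Gja1 (-0.91, adjusted p = 0.239) had values on either side of 0. The other 7 calls held with an estimated correlation (adjusted p between 0.00388 and 0.0140).

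Other groups were not called in astrocytes. Microglia and myeloid markers had 0 of 7 members past the threshold, 1 adjusted over the list alone (median 0.40, adjusted p = 0.0798). Adjusted p was 0.0933 for oligodendrocyte markers, 0.398 for mural and fibroblast markers and 0.641 for neuron markers, whose median (-0.05) lay below 0 while they were tested as higher. It was 0.242 for postsynaptic genes. Of 5 dentate granule markers 1 rose, Pdzd2 (2.39, SE 0.52, adjusted p = 0.0350). Presynaptic genes (median 0.15) and oxidative phosphorylation genes (median 0.07) were tested in the opposite direction to their medians, with adjusted p of 0.852 and 0.602. Mapt, the mouse tau gene, had a value of 1.0 (SE 0.37, adjusted p = 0.224), Prnp, whose promoter drives a widely used form of the P301S transgene, -0.41 (adjusted p = 0.544; -0.24 without non-Tg astrocyte 5), and the apolipoprotein gene Apoe 0.57 (adjusted p = 0.328). In all, 63 of 12130 genes rose and 3 fell, 7 of the former predicted or unnamed. Over all genes tested, the groups of 260 (2.14%) did not overlap, which chance gives for 0.433% of genes; 52 of these were among the 66. The median over all genes was 0.13, but -0.15 with voom and -0.17 without a filter, and the counts with these settings were 124 and 561. With the number of genes detected per library as a covariate, chosen after seeing the data, 6 genes passed, and with a sex marker covariate 15. Xist was at 24.5 ± 9.54 CPM in non-Tg and 74.0 ± 61.9 CPM in P301S astrocytes (1.59, adjusted p = 0.164) and the Y-linked gene Uty at 66.2 ± 26.7 and 32.4 ± 15.2 CPM (-1.03, adjusted p = 0.298). Leaving out any 1 of non-Tg astrocytes 1, 2, 3 and 6 ended the calls of Ptpn4, Tlcd4, Ggta1, Stat2, Gpnmb and Pdzd2. Single libraries moved the count between 27 (without non-Tg 3 or 6) and 136 (without P301S 2).

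**Figure D2:**
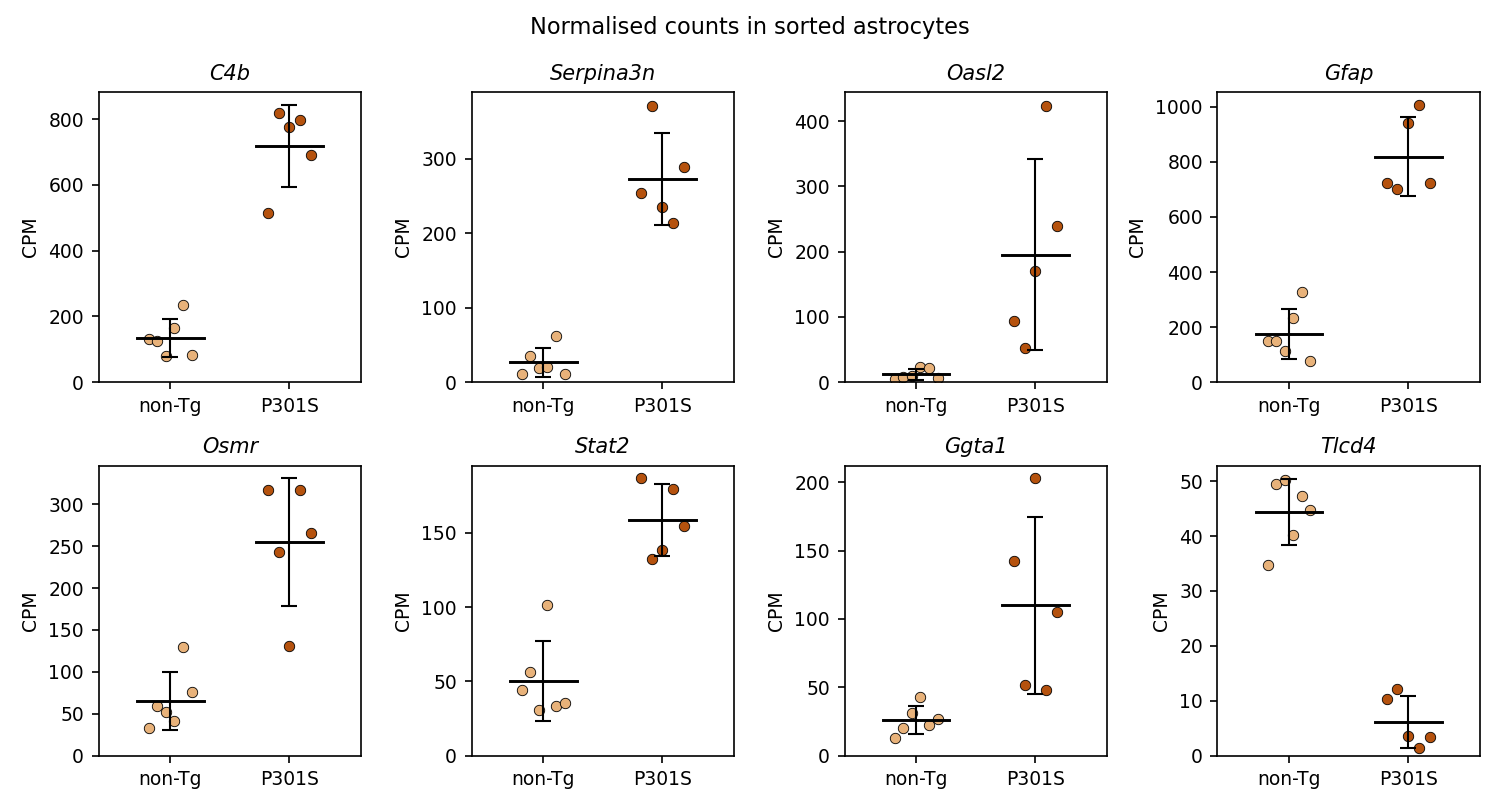
Normalised level in CPM of 8 genes in each P301S (n = 5) and non-Tg (n = 6) astrocyte library, with group means and SD. C4b averaged 719 CPM in P301S and 136 CPM in non-Tg libraries, and Tlcd4 6.15 and 44.4 CPM.

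In neurons 1 gene passed, Ddx60, an interferon-induced RNA helicase gene (ID 234311, GRCm38 chromosome 8 from 61928073 to 62037704). It rose from 1.70 ± 1.26 CPM (n = 8) to 10.6 ± 2.83 CPM (n = 6), a log2 change of 2.61 (SE 0.38, adjusted p = 0.0111), and was above the non-Tg mean in 6 of 6 P301S libraries. Its counts were between 0 and 11 per non-Tg library and between 13 and 28 per P301S library. The 2 groups did not overlap, which chance gives for 0.0666% of genes and which held for 24 of the 10951 tested. Mapt, the mouse gene of the protein that the transgene encodes in its human form, was at 58.4 ± 29.4 CPM in non-Tg and 58.1 ± 13.2 CPM in P301S neurons (-0.02, SE 0.26, adjusted p = 0.989), a value whose sign was positive with voom (0.33). Prnp had a value of 0.06 (adjusted p = 0.968; -0.047 to 0.19 without single libraries) and Apoe of 0.79 (SE 0.59, adjusted p = 0.795), the latter 0.24 without P301S neuron 1. C3 and C4b had too few counts in neurons to be tested.

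Dentate granule neuron markers fell as a list in P301S neurons (10 tested, median log2 change -0.26, adjusted p = 7.96e-04), with 0 past the threshold over all genes and 4 lower adjusted over the list alone. It is the 1 called list in neurons that held with an estimated correlation (adjusted p = 0.0379). With the oligodendrocyte and microglia marker levels as covariates its adjusted p was 0.105, the highest of 28 alternatives. Stxbp6, a SNARE-binding protein gene, was at 132 ± 34.5 CPM in non-Tg and 71.4 ± 16.2 CPM in P301S neurons (-0.88, SE 0.18, adjusted p = 0.121) and C1ql3, a secreted synaptic organiser gene, at 272 ± 90.8 and 137 ± 36.6 CPM (-0.98, SE 0.23, adjusted p = 0.20). Plk5 (-0.95, SE 0.29) and C1ql2 (-0.69, SE 0.24) were also below the non-Tg mean in 6 of 6 P301S libraries. Prox1 (-0.15) and Calb1 (-0.02), a fate regulator of granule neurons and a calcium buffer, were near 0, and 2 of the 10 were above 0. Inhibitory neuron markers were called higher (8 tested, median 0.43, adjusted p = 1.44e-05; adjusted p = 0.209 with an estimated correlation), with 0 past the threshold and 3 adjusted over the list alone. Lhx6, a transcription factor gene of cortical interneurons, had a value of 1.34 (SE 0.33, adjusted p = 0.208) and Gad2, a GABA synthesis gene, of 0.64 (SE 0.21, adjusted p = 0.439).

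Activity-regulated genes were called higher (9 tested, median 0.46, adjusted p = 7.96e-04; adjusted p = 0.209 with an estimated correlation), with 0 past the threshold and 1 adjusted over the list alone. The immediate early gene Arc had a value of 1.18 (SE 0.34, adjusted p = 0.313) and Egr1 of 0.60. Heat shock genes were called (6 tested, median 0.37, adjusted p = 0.0172; adjusted p = 0.209 with an estimated correlation) with 0 past the threshold under either adjustment. Leaving out non-Tg neuron 2 or non-Tg neuron 8 ended this call (highest adjusted p without 1 library 0.107), as did the sex marker covariate. Dnajb1 (0.77) and Hspa8 (0.65), both chaperone genes, had the smallest p values. Astrocyte and microglia markers were also called higher in the P301S neuron libraries, but only as lists with the preset correlation. Astrocyte markers (11 tested, median 0.57, adjusted p = 9.79e-04) had 0 past the threshold and 3 adjusted over the list alone, and genes of astrocyte transport and metabolism (10 tested, median 0.63, adjusted p = 1.04e-04) had 0 under either adjustment. For both the adjusted p with an estimated correlation was 0.309. Gfap had a value of 1.72 (SE 0.47, adjusted p = 0.254), Aqp4 of 1.07 (SE 0.39) and Slc1a2 of 0.36. Microglia and myeloid markers (7 tested, median 0.77, adjusted p = 0.0155; adjusted p = 0.412 with an estimated correlation) had 0 past the threshold under either adjustment, with C1qc at 1.31 (SE 0.63) and Itgam at 0.86, or 0.65 and 0.31 without P301S neuron 1. The microglia list was not called without P301S neuron 1 (adjusted p = 0.250; highest over 28 alternatives 0.852), the library with the highest Itgam level (84.9 CPM).

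Other groups were not called in neurons. Adjusted p was 0.411 for neuron markers, 0.965 for excitatory markers, 0.791 for presynaptic genes, 0.982 for postsynaptic genes, 0.965 for oxidative phosphorylation genes and 0.512 for unfolded protein and integrated stress genes. The medians of presynaptic (-0.0037) and postsynaptic genes (-0.03) lay below 0, while both were tested as higher. Complement genes (adjusted p = 0.0725) were not called, nor were cholesterol synthesis genes (adjusted p = 0.0725), of which 13 of 14 had values below 0 with a median of -0.21. In all, 1 of 10951 genes rose and 0 fell by edgeR, with 846 at an unadjusted p under 0.05 (333 higher, 513 lower); DESeq2 called 49 and voom 41. Without the 2 non-Tg neuron libraries of another identifier range, a possible batch that holds non-Tg libraries alone, 38 genes passed, and without non-Tg neuron 8 alone 23. Without non-Tg neuron 2, P301S neuron 4 or P301S neuron 5, 0 passed (adjusted p of Ddx60 0.0625, 0.0527 and 0.0586; 1.88e-07 to 0.0625 over 25 alternatives).

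**Figure D3:**
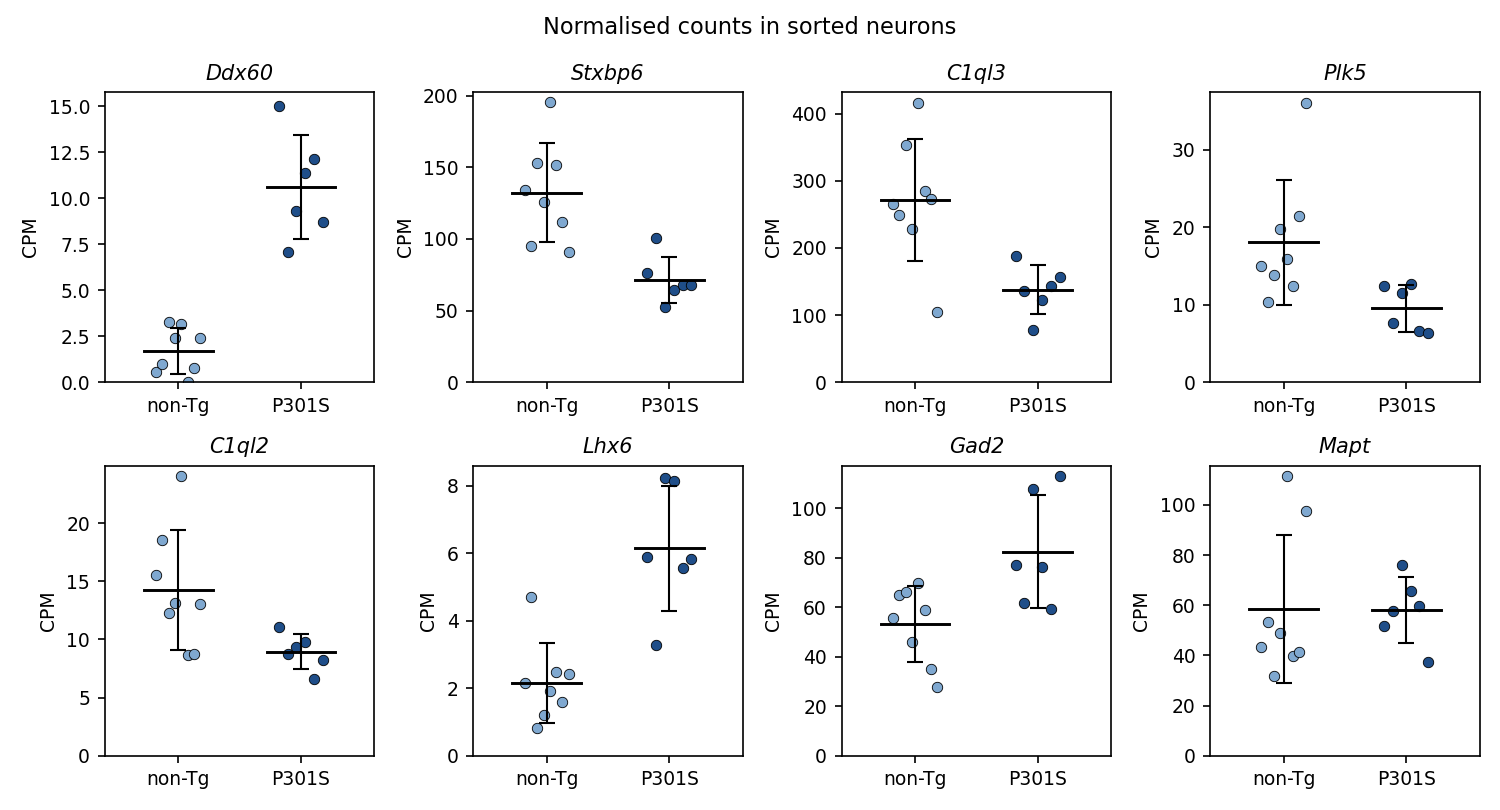
Normalised level in CPM of 8 genes in each P301S (n = 6) and non-Tg (n = 8) neuron library, with group means and SD. Ddx60 averaged 10.6 CPM in P301S and 1.70 CPM in non-Tg libraries, and Mapt 58.1 and 58.4 CPM.

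**Figure D4:**
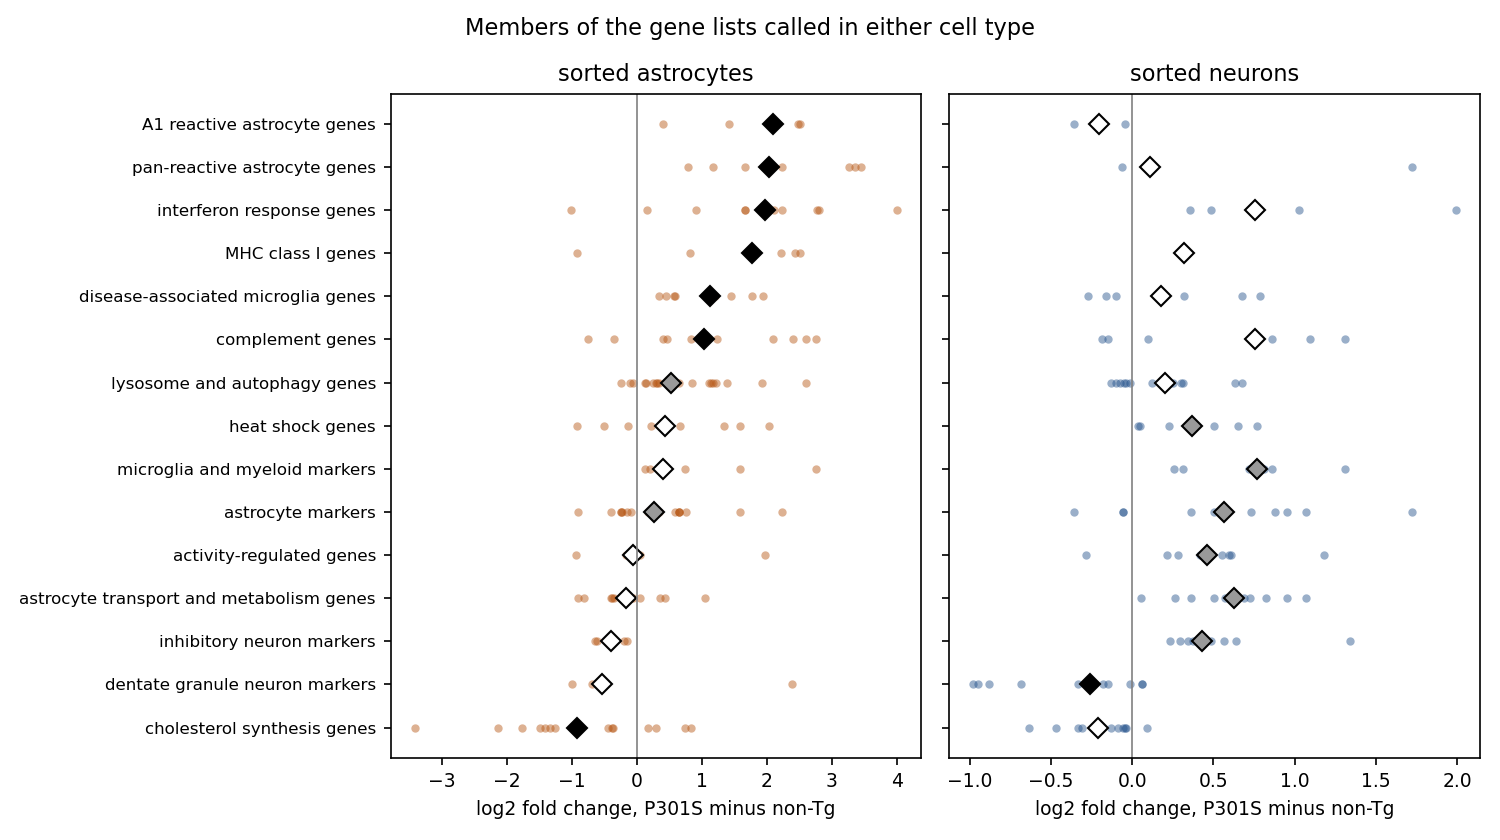
Log2 fold change of P301S against non-Tg for the tested members of each gene list (dots) and their median (diamond) in neurons and in astrocytes, on axes of different scale. Black diamonds mark lists called with the preset and the estimated correlation, grey ones lists called with the preset correlation alone and white ones lists not called; pan-reactive astrocyte genes had a median of 2.03 in astrocytes and dentate granule neuron markers -0.26 in neurons.

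The genotype effect was larger in astrocytes than in neurons for pan-reactive and A1 astrocyte genes as lists. Serpina3n was the 1 member of these lists called by itself. Serpina3n was at 30.5 ± 22.6 CPM in non-Tg and 317 ± 72.2 CPM in P301S astrocytes, but at 14.3 ± 4.57 and 13.8 ± 4.01 CPM in neurons, a log2 difference of the effects of 3.43 (SE 0.49, adjusted p = 7.39e-04; scaled over all 25 libraries). Ssc5d (3.51, SE 0.61, adjusted p = 0.00711), the actin-binding synaptopodin gene Synpo (4.10, SE 0.75, adjusted p = 0.0137) and Sbno2 (3.40, SE 0.64, adjusted p = 0.0159), a transcriptional regulator gene, also had the larger effect in astrocytes. Pex5l, Plcl2, Chl1 and Net1 completed the 8 with the smallest p (1.62 to 4.12), but Plcl2, Chl1 and Net1 were not called when any 1 of the 6 P301S neuron libraries was left out. Deptor, an mTOR inhibitor gene, had the lower effect in astrocytes (-2.76, SE 0.56, adjusted p = 0.0240), from 41.6 ± 15.1 to 10.2 ± 4.48 CPM there and from 5.89 to 9.92 CPM in neurons; it was not called without P301S neuron 2, P301S neuron 3 or non-Tg neuron 3. Another 6 lower genes, Dcdc5, Pgr, Snai2, Ptpn5, Ankrd49 and Cnrip1 (-5.82 to -3.08), averaged between 0.0748 and 2.05 CPM in P301S astrocytes. These levels were below or near the floor of 3 counts, so the sizes of the differences are uncertain. For Ddx60 no difference of the effects was called (-0.18, SE 0.50, adjusted p = 0.913), nor for Gfap (0.51, adjusted p = 0.750) or C4b (1.39, adjusted p = 0.383).

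Among lists, pan-reactive genes differed towards astrocytes (10 tested, 1 past the threshold, median 1.24, adjusted p = 2.75e-10), as did A1 genes (median 1.26, adjusted p = 0.00207) and interferon response genes (median 1.09, adjusted p = 1.52e-04). Cholesterol synthesis genes (median -0.79, adjusted p = 0.00114) and inhibitory neuron markers (median -1.22, adjusted p = 0.00114) differed the other way. MHC class I, disease-associated microglia, complement and lysosome genes were called towards astrocytes, and astrocyte transport and metabolism genes the other way. These 5 were not called with an estimated correlation (adjusted p from 0.0561 to 0.428). In all, the effect was higher in astrocytes for 29 and lower for 27 of 14197 genes. The fit gave each gene 1 spread for both cell types, with a biological coefficient of variation of 0.539. Fitted apart, that coefficient was 0.726 in astrocytes and 0.270 in neurons, so the p-values may be too small for differences that arise in astrocytes. In a fit of all 25 libraries the genotype calls in astrocytes likewise went from 66 to 1682. The count was 10 with voom and 425 with DESeq2, and it ran from 9 without P301S neuron 3 to 522 without P301S astrocyte 1.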

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

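The tests of microglial RNA in P301S astrocyte libraries, of fewer counts, of astrocyte RNA as the origin of Ddx60 and of the share of dentate granule neurons were chosen only after the results were seen, as were the fits with genes detected as a covariate and without P301S astrocyte libraries 3 and 4.

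The 66 genes called between P301S and non-Tg astrocytes stand beside libraries that differ in quality: P301S libraries detected fewer genes (difference -2677 at 1e+06 counts each, so not through fewer counts, and -2899 without Malat1 and mitochondrial genes, so not through a larger share of those). The real split gave 66 calls and the highest of the other splits 3 (1 of 100, the real one included, the smallest share these splits can give). The wide margin argues against chance for the count, though the splits were not adjusted for the other results tested this way. Splits cannot separate genotype from the quality that differed with it. With genes detected as a covariate the median log2 change of the 63 higher genes was 1.77 (bootstrap interval over genes 1.51 to 2.15). It was 2.10 without the covariate, and 63 of 63 stayed above 0. Lower complexity is not excluded by this, because these genes were picked as higher in the same libraries and genes detected moved with genotype. The calls fell to 6, as the median SE grew from 0.403 to 0.533. Without P301S astrocyte libraries 3 and 4, 42 genes passed, 28 of them among the 66. Microglia and myeloid markers (7 tested) had a median of 0.40 and together rose from 80.4 to 129 CPM. That gain of 48.4 CPM was smaller than those of Gfap (644) and C4b (584). The 63 higher genes were picked for their change and the markers were not. Their medians therefore cannot decide on microglial RNA for the other calls. Fewer genes passed with oligodendrocyte and microglia marker levels as covariates, and with a sex marker covariate. A response of astrocytes to the transgene stays a hypothesis, and quality or sex composition tied to genotype may have shaped single calls. The astrocytes were sorted by Gfap, whose own RNA rose from 175 to 820 CPM. Whether the sort took the same kinds of astrocytes in both genotypes was not tested.

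Ddx60 was the 1 gene called in neurons, and the count itself cannot be set apart from chance: the real split gave 1 call and the highest other 1495, with 6 of 100 splits giving at least 1. The 2 splits with the most calls (1495 and 1450) set non-Tg neuron 8 with P301S neurons 3, 4 and 5, which points to a structure among these libraries. The gain was 4.91% of the mean Ddx60 level in P301S astrocytes (interval 3.0 to 9.78). The largest such share among 16 astrocyte markers was 1.14%. These shares argue against astrocyte RNA of the average make-up of those libraries as the origin of the gain. Ddx60 counts ran from 130 to 809 across the P301S astrocyte libraries, so RNA from astrocytes richer in Ddx60 than average is not excluded. Microglial RNA cannot be told apart from expression in neurons, because the log2 change with oligodendrocyte and microglia marker levels as covariates was 2.29 (SE 0.486, adjusted p = 0.0551; range 1.88e-07 to 0.0625 over 25 alternatives) and the microglial level of Ddx60 was not measured here. Without P301S neuron 1, the library with the most microglial markers, Ddx60 in neurons had a log2 change of 2.50 (adjusted p = 0.0276), and an interferon response of neurons is a hypothesis that may be followed up.

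Dentate granule neuron markers were lower as a list in P301S neurons. The real split gave a camera p of 0.000168 and the smallest of the other splits 0.000247 (1 of 100, the real one included). The list was 1 of 19 tested in neurons and the splits were not adjusted for that, so chance is not excluded. A smaller share of dentate granule neurons in the P301S sorts would lower all markers together, and 8 of 10 had values below 0, with Prox1 at -0.15 and Calb1 at -0.02. That does not decide between a smaller share and lower expression within these neurons, so both may contribute and neither was separated by the design. With oligodendrocyte and microglia marker levels as covariates the list was not called (adjusted p = 0.105, against 1.95e-05 to 0.105 over 28 alternatives).

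For the other results of splits, the 56 genes whose effect differed between cell types came with a highest other split of 52 (1 of 100, the real one included). The margin was narrow, and leaving out 1 library moved the real count between 9 and 522. The splits therefore do not exclude chance for this count. Chance is not excluded for the number of lists called. In neurons 7 were called, with a highest other split of 10 (10 of 100). In astrocytes 9 were called, with a highest other split of 10 (7 of 100). The other astrocyte splits that reached 9 kept most of the genotype grouping or its mirror image. Examples set non-Tg astrocytes 1 to 5 against the rest (9 lists) or grouped P301S astrocytes 2 to 5 with non-Tg astrocyte 6 (10 lists). The count ignores direction, so the splits cannot decide on chance for the astrocyte lists. The genes called higher in astrocytes had a median log2 change of 0.14 in neurons, over 33 tested there with 24 above 0, and chance cannot be excluded (24 of 100 splits as high, highest 0.42).

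Single libraries stood far from the others of their group in 27 of 178 sets of values examined. For normal and independent values the rule flags about 1 in 20 sets, or 8.9. The flagged values were all the highest of their group and the sets share libraries, so 8.9 is not a firm expectation by chance. In P301S neuron 1 the levels of Itgam (84.9 CPM), Csf1r (61.4), Cx3cr1 (101), Glul (32.6) and Apoe (30.7) and the mitochondrial share (2.43%) were the highest of the group. P301S astrocyte 3 had the highest H2-D1 (77.0 CPM), C1qb (108), Cyp51 (66.2), Dlg3 (150) and Cd68 (41.4), and P301S astrocyte 4 the highest B2m (289). Among non-Tg astrocyte libraries, number 4 had the highest Ssc5d (10.3 CPM), Dsp (25.7), B2m (49.2), Serping1 (20.5) and Stat2 (102), number 5 stood apart for Ctsb (157) and number 6 for Ptpn4 (231). Among non-Tg neuron libraries, number 8 had the highest Plk5 (36.0 CPM), Arc (22.5) and Npas4 (62.2), and number 2 stood apart for Lhx6 (4.69), number 4 for Gfap (10.2), number 5 for Hsp90aa1 (64.7) and number 6 for Glul (24.1). Dusp1 was highest in P301S neuron 5 (16.7 CPM).

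The difference of the genotype effect between astrocytes and neurons passed its test for 56 genes. Among those named, it was 3.43 for Serpina3n, 3.51 for Ssc5d, 4.10 for Synpo, 3.40 for Sbno2, 2.46 for Pex5l, 2.68 for Plcl2, 1.62 for Chl1 and 4.12 for Net1 on the log2 scale. It was -5.82 for Dcdc5, -4.67 for Pgr, -4.72 for Snai2, -4.73 for Ptpn5, -2.76 for Deptor, -3.08 for Ankrd49 and -3.32 for Cnrip1.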

How the results depend on the processing

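The fits with the authors' size factors, with genes detected as a covariate, without P301S astrocyte libraries 3 and 4, without Malat1 and mitochondrial genes and with a minimum of 3 tested members, and the lists without the 2 non-Tg neuron libraries of the other identifier range, were chosen only after the data were seen. No paired analysis was possible because the labels give no animal or replicate numbers, and every setting fixed in advance was run. C4b, Serpina3n and Ssc5d in astrocytes passed in all 23 alternatives, with a highest adjusted p of 0.0393, and Serpina3n, Ssc5d, Synpo and Sbno2 did so for the difference between cell types in all 31. The pan-reactive, A1, interferon, disease-associated microglia, complement and cholesterol lists in astrocytes were called in all 26; the MHC class I list was not called with the sex covariate (adjusted p 0.0675, the highest of 26). In astrocytes 82 alternatives of named genes lost a call, 68 gained one, and 967 stayed on their side of the threshold, uncalled genes included. Of 23 alternatives the call was lost in 14 for Ptpn4, 9 each for Ggta1, Stat2 and Pdzd2, 8 for Gpnmb, 7 for Tlcd4, 6 for Dcdc5, 3 for Aspg, 2 for C4a and 1 each for Gfap, Fxyd1 and Osmr (genes detected as a covariate) and Oasl2 (sex covariate). For the difference between cell types, of 31 it was lost in 13 for Chl1, 12 each for Plcl2 and Net1, 5 for Cnrip1, 4 for Deptor, 2 each for Ankrd49 and Ptpn5 and 1 each for Pex5l, Pgr and Snai2 (voom), and in 1 of 26 for Dcdc5 (voom). For the P301S against non-Tg in neurons count, 1 gene, the value was 49 with DESeq2, 41 with voom, 17 without a filter, 10 with the filter at 1 CPM, 24 with the cell marker covariates (Ddx60 not among them), 38 without non-Tg neurons 5 and 8, and 0 to 23 without 1 library each. It was 0 without non-Tg 2, P301S 4 or P301S 5, 2 without non-Tg 6, 3 without P301S 1, 5 without P301S 6, 8 without non-Tg 5 and 23 without non-Tg 8. The 7 gene lists called in neurons were 11 without a filter, 11 with the filter at 1 CPM, 13 with all 25 libraries in 1 fit, 2 with the cell marker covariates, 1 with an estimated correlation, 1 with fry, and 5 (without non-Tg 2 or 8) to 11 (without non-Tg 3). The 66 genes in astrocytes were 440 with DESeq2, 124 with voom, 561 without a filter, 1682 with all 25 libraries in 1 fit, 15 with the sex covariate (13 shared), 30 with the cell marker covariates (21 shared), 6 with genes detected as a covariate and 42 without P301S libraries 3 and 4. They were 27 without non-Tg 3 or 6, 29 without non-Tg 1 or 2, 108 without P301S 1 and 136 without P301S 2. The 56 genes that differed between cell types were 425 with DESeq2, 10 with voom (8 shared) and 266 without P301S astrocyte libraries 3 and 4. Without 1 library each they ran from 9 (without P301S neuron 3) to 522 (without P301S astrocyte 1). They were 269, 98, 198 and 183 without P301S astrocytes 2, 3, 4 and 5 and 101 and 114 without non-Tg astrocytes 4 and 5, and 9 to 23 without any neuron library other than non-Tg neuron 5 (52). The genes that differ between neurons and astrocytes in non-Tg numbered 6598 to 6681. The sign turned for Mapt in neurons with voom (0.33), all 25 libraries in 1 fit (0.0022), the cell marker covariates (0.11), without non-Tg neurons 5 and 8 (0.42) and without single libraries (-0.12 to 0.16). It turned for Prnp in neurons with voom (-0.0027), the sex covariate (-0.014), the cell marker covariates (-0.36) and without single libraries (-0.047 to 0.19), and for Cx3cr1 in neurons without P301S neuron 1 (-0.015, in a range to 1.09). In astrocytes it turned for Gabarap with voom (-0.38), Dlg3 with the cell marker covariates (-0.033) and Camk2a with genes detected as a covariate (-0.32). The cause of these changes was not tested. C3 (0 to 5 counts per library) and C4b (0 to 20) were too low to test in neurons, and whether more depth would change that was not tested. In simulated data edgeR recovered 25% of genes changed by 2 on the log2 scale in astrocytes and 99% in neurons; the astrocyte libraries are the deeper ones, and their biological coefficient of variation was 0.726 against 0.270 in neurons.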

Other observations

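Interferon-induced genes had higher values in P301S neurons beyond Ddx60, in a test chosen only after the data were seen. The interferon response list has 4 tested members in neurons, below the minimum of 5; with a minimum of 3 it was called (median log2 change 0.75, adjusted p = 1.72e-05; adjusted p = 0.00933 with an estimated correlation), with 0 past the threshold over all genes and 2 adjusted over the list alone. Ifit1, an interferon-induced antiviral gene, had a log2 value of 1.99 (SE 0.37, adjusted p = 0.0611), the transcription factor gene Stat2 of 0.48 and Irf9 of 0.36. In the same P301S neuron libraries astrocyte markers (median 0.57, adjusted p = 9.79e-04) and microglia and myeloid markers (median 0.77, adjusted p = 0.0155) were called higher as lists, each with 0 members past the threshold and neither with an estimated correlation (adjusted p = 0.309 and 0.412). The microglia list was not called without P301S neuron 1 (adjusted p = 0.250; highest over 28 alternatives 0.852). RNA of those cells was not excluded as the origin of these values. In P301S astrocytes Ddx60 rose by 2.43 (SE 0.41, adjusted p = 0.00631), and more interferon-induced genes among the 66 called there, named after their values were seen, were Ifi27 (2.65), Rnf213 (1.62), Gbp6 (3.25), Gbp3 (2.57), Gbp7 (1.83), Irgm1 (2.72) and Mx2 (3.01). Cxcl10, a chemokine gene, rose by 3.44 (SE 0.73, adjusted p = 0.0332), and Art3, a gene that overlaps it, had counts equal to 14.9% of those of Cxcl10.

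Also called in P301S astrocytes, and named after their values were seen, were the metallothionein genes Mt2 (2.02) and Mt1 (1.86), the protease inhibitor gene A2m (2.08), the prostaglandin synthase gene Ptgds (3.36), the nuclear RNA Neat1 (1.70), Myc (3.09) and the mitochondrial gene ND4 (1.56), in libraries whose mitochondrial share was 7.72% against 4.04% in non-Tg.

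In neurons, 20 genes passed in each of DESeq2, voom and the fit without non-Tg neurons 5 and 8, a set formed after the values were seen. They included Ddx60, Ifit1, Stxbp6, C1ql3, Thsd7a, Slc5a12, Ndst3, Negr1, Hlf and Pter. In the simulated neuron counts false calls numbered 24 with DESeq2, 10 with voom and 14 with edgeR.

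The closest pair of libraries within a group had a chi-squared statistic per degree of freedom of 1.84 (non-Tg neurons), so no library was a copy of another at counting error. Every library held counts of markers of both sexes, Xist (29 to 272) and the Y-linked gene Ddx3y (55 to 254). These counts argue against libraries of 1 animal each, unless RNA or reads were carried over between libraries, which was not tested. In astrocytes the level of Xist was 24.5 ± 9.54 CPM in non-Tg (n = 6) and 74.0 ± 61.9 CPM in P301S libraries (n = 5; log2 value 1.59, adjusted p = 0.164). The Y-linked genes there had log2 values of -1.03 (Uty, adjusted p = 0.298), -0.71 (Eif2s3y), -0.31 (Kdm5d) and 0.09 (Ddx3y), and with the sex marker covariate 15 of 12130 genes passed in place of 66. In neurons Xist had a value of 0.13 and Uty of -0.08.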
